A study of Mus musculus with 6 samples.

How the data were processed

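LSK bone marrow cells from mice with inducible HOXA10 were cultured without doxycycline or with 0.1 or 0.5 µg/ml, and 6 Affymetrix MOE430 v2 arrays were measured, 2 per concentration. Groups and replicate numbers came from the sample titles. Per the labels and the series' design text, RNA from 2 independent experiments was labelled with the two-cycle protocol and scanned with a GeneChip Scanner 3000. Nothing used here says which cultures or animals each number stands for, so the spread between the arrays of a group may be partly technical.

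The values are linear probe set intensities as deposited by the authors. The design text names GC-RMA in GeneSpring 7.2, a floor of 0.01, division by the median of 100 positive control genes and division by the untreated samples. The deposited values do not show these steps, since 0 values lie at or below the floor and array medians run from 49.1 to 97.4. Which summary made each probe set's value is not given in the sources used here. The number of arrays limits the precision.

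Of 45101 probe sets, 64 are controls and 49 have an empty cell on some array. The other 44988 were log2 transformed without an offset and quantile normalized between arrays with limma 3.58.1 in R 4.3.3. The design fixed before the data were examined had taken the deposited values as already normalized between arrays. They were not, so quantile normalization became the main setting and the deposited scale an alternative. The platform annotation lists 35890 probe sets, 34958 with 1 gene and 932 with several, and 9160 probe sets other than controls are unnamed here. Those with several genes named none. Of the annotation's gene identifiers, 99.4% were found in the reference table, and no symbol differed. The 34910 usable probe sets with 1 gene gave 18181 genes, each read by its brightest probe set over all arrays; 9000 genes have more than 1, and values of the next brightest are given where they part. The 9146 unnamed probe sets tested on their own gave 1, 0 and 1 calls for 0.1 against 0, 0.5 against 0 and 0.5 against 0.1 µg/ml.

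Each comparison was a contrast in 1 limma fit of all groups, two-sided, with a mean-variance trend, 3 residual and 2.59 prior degrees of freedom, and Benjamini-Hochberg adjustment at 0.05 over all genes. For 28 gene lists written before the data were examined, the shift was tested against all other genes with camera at a preset correlation of 0.01, adjusted over 81 tests of 27 lists. The other list had under 3 measured members. With a correlation estimated from the residuals no list passed, and the lowest adjusted p was 0.48. Single members were adjusted over all genes and, separately, over the list alone. The latter was done within each list and comparison, with no adjustment across lists, and so is a weaker criterion. Many members are said below to rise or fall on that criterion only, without having passed over all genes. In 19 of the 69 tests that did not pass, a list's median, mean and test differed in sign, and in 0 of the 12 that passed.

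Genes were named by a rule fixed before the data were examined. It took the 12 largest differences in each direction that passed with no overlap between groups (6 for 0.5 against 0.1 µg/ml), filled up with the smallest unadjusted p at 2-fold or more, left out clones and predicted genes, and added Hoxa10, Gata1, Gfi1, Hlf, Meis1, Mecom, Dkk1 and up to 4 members of each list. The text reports part of these genes.

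The fit was tested on simulated data for 0.5 against 0 µg/ml. Of 18181 genes, 200 were changed, all drawn from the brighter part of the genes. Changes of 1, 2, 3 and 4 on the log2 scale were recovered in 18.4%, 57.2%, 86% and 94% of cases over 5 simulations, with 8.6 false calls each. The noise followed the moderated variances and was equal in all groups, so recovery for dim genes or unequal spread was not shown. Simulated lists of 25 genes passed an unadjusted threshold in 100% of cases when shifted by 0.5 on the log2 scale and in 2.5% when flat. The simulated noise was independent between genes, so these rates do not bear on correlation within real lists.

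Alternatives were other scalings, a replicate block, no trend, a robust prior, dim genes left out, an offset of 30.2, other uses of several probe sets, fits of only the groups compared, other thresholds and each array left out. With 1 array left in a group, limma takes it to vary like the other groups. Such a fit also has fewer residual degrees of freedom for every comparison. A call can thus end in a comparison that does not use the array left out. Scaling to 24 poly-A spike-in probe sets and a count of genes apart in both of their brightest probe sets were added after the data were seen, as were the simulated overlap of calls and the comparison of dim groups with the 25th percentile. When the alternatives were first compared, a list's direction was read from its absolute median and every list member counted as a named result; this was changed afterwards to the median relative to all genes and to the genes the text names.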

Results

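LSK cells, bone marrow cells that lack mature lineage markers and carry Sca-1 and c-Kit, hold the hematopoietic stem cells and early progenitors of the mouse. They were sorted from rtTA-HA10 mice, in which rtTA, a transactivator that doxycycline switches on, controls HOXA10, a homeobox transcription factor. They were kept for 72 hours in serum-free medium with SCF, FLT-3 and TPO, either without doxycycline or with it at 0.1 µg/ml or at 0.5 µg/ml. RNA was then measured on Affymetrix MOE430 v2 arrays, which read most mouse transcripts. Each concentration had 2 arrays from 2 independent experiments, 6 arrays in all, and this number limits the precision of every value. The comparisons ask which genes respond to a lower and to a higher setting of the inducer, and whether the settings differ. Cells without the transgene that received doxycycline were not analysed here.

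The deposited arrays differed in brightness before any normalization. Array medians were 90.8 ± 9.33 (SD, n = 2) without doxycycline, 72.2 ± 14.3 at 0.1 µg/ml and 51.2 ± 2.90 at 0.5 µg/ml. The poly-A spike-ins, bacterial transcripts normally added to the RNA before labelling, had geometric means of 688 ± 150, 745 ± 109 and 2105 ± 235. The Gapdh 3' to 5' probe set ratio, which rises as a labelled transcript is shorter, was 2.23 ± 0.12, 2.42 ± 0.09 and 3.92 ± 0.91 in the same order, and the Actb ratio 1.75 ± 0.13, 1.70 ± 0.21 and 2.21 ± 0.44. Differences below are between quantile-normalized log2 intensities, in which the median gene moved by 0.07 at 0.1 µg/ml and 0.01 at 0.5 µg/ml against the control. Without normalization the median gene moved by -0.23 and -0.94, and all list shifts quoted for that scale are relative to it. With poly-A scaling it moved by -0.36 and -2.57.

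**Figure D1:**
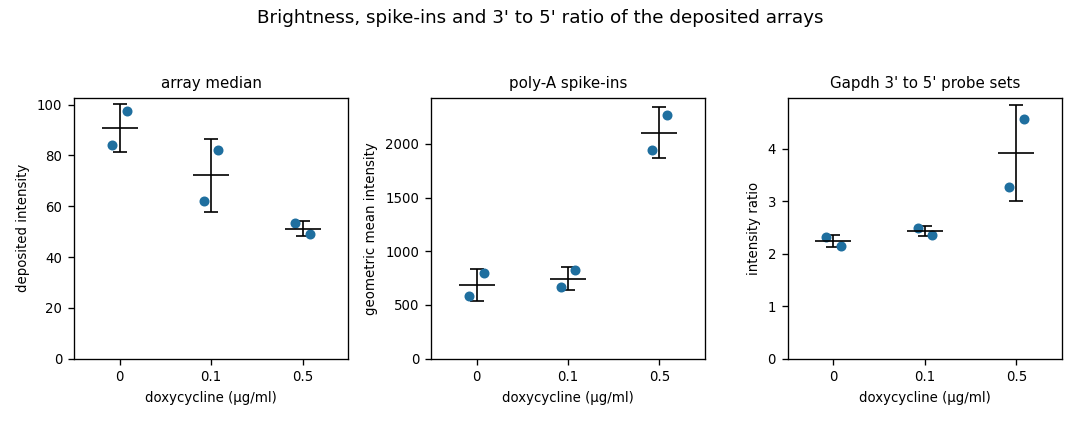
Array median (deposited intensity), geometric mean of the poly-A spike-in probe sets (intensity) and ratio of the Gapdh 3' to 5' probe sets for each of the 6 arrays, against doxycycline in µg/ml. Points are arrays and bars the mean ± SD of 2 arrays. The Gapdh ratio was 3.28 and 4.57 on the arrays at 0.5 µg/ml and at most 2.49 on the others.

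Hoxa10 itself was read by 2 mouse probe sets of middling brightness. The brighter had log2 intensities of 6.08 ± 0.38 (SD, n = 2) without doxycycline, 6.39 ± 0.45 at 0.1 µg/ml and 7.39 ± 0.52 at 0.5 µg/ml. Its log2 difference was 0.31 ± 0.46 (SE) at 0.1 µg/ml and 1.31 ± 0.46 at 0.5 µg/ml (adjusted p = 0.38, limma). After normalization both arrays at 0.5 µg/ml lay above both controls. In the values as deposited these groups overlapped, with intensities of 67.0 and 116.6 in the controls and 149.8 and 85.1 at 0.5 µg/ml. The other probe set gave normalized log2 differences of -0.60 and -0.51. Neither passed, the other being tested with every probe set on its own. The labels do not say whether the transgene is mouse or human, so these probe sets may not read it.

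At 0.1 µg/ml, genes of megakaryocytes and platelets were lower. The list median was -0.55 (log2, 24 measured members) and 20 members lay below 0 (camera adjusted p = 1.2e-07, and adjusted p = 0.57 with an estimated correlation). Adjusted over the list alone, 7 members fell. Adjusted over all genes, none did. Among them Pf4, the platelet chemokine PF4, fell by 1.65 ± 0.28 on the log2 scale (SE). Itga2b, the CD41 subunit of the fibrinogen receptor, fell by 1.09 ± 0.21, and Vwf, which encodes von Willebrand factor, fell by 2.73 ± 0.49. Gp1bb, a subunit of the platelet receptor for it, fell by 2.20 ± 0.50, while its next brightest probe set gave -0.03. Their adjusted p over the list alone was 0.019 for Pf4, Itga2b and Vwf and 0.033 for Gp1bb. The list median was -0.32 without the first or without the second control array and -0.34 with every probe set on its own. The poly-A spike-ins were 1.09-fold and the Gapdh ratio 1.08-fold those of the controls at this concentration.

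Genes tied to hematopoietic stem cells went both ways at 0.1 µg/ml. Adjusted over the list alone, 2 members of that list rose: Procr, the stem cell surface marker EPCR, 4.84-fold (log2 2.28 ± 0.42) and Gfi1, a transcriptional repressor, 2.08-fold (1.06 ± 0.20). Vwf, which sits on this list too, fell. As a whole the list gave a median of 0.12 (30 members, adjusted p = 0.70). In the list of monocytes, macrophages and dendritic cells, Ccr2, a chemokine receptor of monocytes, rose 1.92-fold (0.94 ± 0.13) and Fcgr1, the high-affinity IgG receptor, fell 4.12-fold (-2.04 ± 0.28), both with adjusted p = 0.0060 over the list alone. The next brightest probe set of Fcgr1 gave 1.34, the opposite direction, and that of Ccr2 0.63. Neither passed over all genes, and the list median was 0.10 (adjusted p = 0.81). None of the other 24 lists passed at 0.1 µg/ml. Erythroid genes had a median of -0.14 (33 members, adjusted p = 0.31) and interferon-stimulated genes 0.24 (26 members, adjusted p = 0.48).

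Of 18181 genes tested with limma, 4 passed an adjusted p of 0.05 at 0.1 µg/ml. Pygm, the muscle form of glycogen phosphorylase, rose by 4.28 ± 0.27 on the log2 scale (SE, adjusted p = 0.036) and the clone 4933411E08Rik by 5.12 ± 0.31 (adjusted p = 0.036). Cmbl, a hydrolase, fell by 5.84 ± 0.29 (adjusted p = 0.033) and the clone C430002N11Rik fell by 6.22 ± 0.35 (adjusted p = 0.033). The clones were named after their values were seen. The dimmer group of 4933411E08Rik, Cmbl and C430002N11Rik had a mean log2 intensity of 4.78, 4.55 and 4.38, below 4.95, the 25th percentile of all values, and no background call was used, so no fold is given. With an offset of 30.2 the differences were 3.48 for Pygm, 4.09 for 4933411E08Rik, -4.68 for Cmbl and -4.95 for C430002N11Rik, and all 4 passed. Each call held under 8 or 9 of 17 alternatives. Sprr1b, a cornified envelope protein, at 4.73 ± 0.36, Cyp2d22, a cytochrome P450, at 4.13 ± 0.35, and Tfap2a, a transcription factor, at 3.12 ± 0.34 were higher without passing (adjusted p = 0.057, 0.066 and 0.16), the first 2 from control means of 3.81 and 4.19. Abcg1, a sterol exporter, at -2.56 ± 0.25 and Opn4, the photopigment melanopsin, at -3.54 ± 0.29 were lower without passing (adjusted p = 0.12 and 0.066). Cars2 was at -6.40 ± 0.48 and Mt4 at -4.10 ± 0.35, also without passing (adjusted p = 0.057 and 0.066). Their means were 11.06 and 7.94 in the controls, 4.65 and 3.84 at 0.1 µg/ml and 10.75 and 7.74 at 0.5 µg/ml. Dennd2a, Hid1, Hsf2bp, Lrig3 and Reep4, lower at 0.1 µg/ml without passing, also stood near the control mean at 0.5 µg/ml. Abcg1, Opn4, Mfap2 and Cmc2 stayed below it. The next brightest probe sets gave 0.02 for Cyp2d22, 0.69 for Tfap2a, -0.32 for Abcg1, 0.10 for Opn4 and 0.02 for Cars2. They gave 0.59 for Dennd2a, the opposite direction, -0.18 for Hid1, -0.19 for Hsf2bp and -0.61 for Lrig3. For Mfap2 and Cmc2 they gave -1.66 and -0.01, and Reep4 has 1 probe set. By size alone, 599 genes were at least 2-fold higher and 920 at least 2-fold lower with no overlap between the groups. These counts were 275 and 1596 in the values as deposited and 204 and 2015 with poly-A scaling. The total of 1519 became 2654 without the first control, 2362 without the second, 2357 without the first array at 0.1 µg/ml and 2389 without the second. Groups of 2 were apart for 40.7% of genes, where chance gives 33.3%. With any single array left out, at most 1 gene passed. An unadjusted p below 0.05 (limma) was reached by 1003 of 18181 genes, little above the rate of 0.05 at which unchanged genes reach it. At 0.5 µg/ml it was reached by 2176 genes.

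At 0.5 µg/ml the loss of megakaryocyte and platelet transcripts was larger in size. The list median was -0.77 (18 of 24 members below 0, camera adjusted p = 5.1e-07, and adjusted p = 0.57 with an estimated correlation). Adjusted over the list alone, 12 members fell, and 2 of them also passed over all genes. Those were Pf4, which fell 9.50-fold (log2 -3.25 ± 0.28 SE, adjusted p = 0.046), and Itga2b, which fell 5.04-fold (-2.33 ± 0.21, adjusted p = 0.047). Their calls over all genes held under 9 and 7 of 17 alternatives. Pf4 stood at 12.74 ± 0.22 (SD, n = 2), 11.09 ± 0.39 and 9.49 ± 0.44 with rising concentration. Gp1bb fell by 3.13 ± 0.50 (adjusted p = 0.0054 over the list alone), though it ended at 4.38, below the 25th percentile of intensity (4.95), and its next brightest probe set gave 0.26. Rab27b, a GTPase of platelet granule release, fell by 2.53 ± 0.31 (0.0020), with -0.73 from its next brightest probe set. Without the first control array the list median was -0.34. Gata1, the master regulator of the erythroid and megakaryocytic lineages, was at -1.80 ± 1.25 and did not pass (adjusted p = 0.62), with its arrays at 0.5 µg/ml spread widely (SD 2.59).

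Among erythroid genes, 4 of 33 fell when adjusted over the list alone. The list as a whole did not pass (median -0.19, camera adjusted p = 0.052, and adjusted p = 0.57 with an estimated correlation). Hemgn, a nuclear protein of erythroid precursors, fell by 1.44 ± 0.17 (adjusted p = 0.0060 over the list alone). Zfpm1, the GATA1 cofactor FOG1, fell by 1.60 ± 0.34 and Epor, the erythropoietin receptor, fell by 1.84 ± 0.41 (both 0.047), the latter to a mean of 4.08, below the 25th percentile of intensity (4.95).

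Stem cell genes were higher at 0.5 µg/ml. The list median was 0.45 (23 of 30 members above 0, camera adjusted p = 5.3e-04, and adjusted p = 0.72 with an estimated correlation). Adjusted over the list alone, 8 members rose and 3 fell, none of them over all genes. Procr rose 14.5-fold (3.86 ± 0.42), Gfi1 rose 4.15-fold (2.05 ± 0.20) and Hlf, a transcription factor of stem cells, rose 3.16-fold (1.66 ± 0.19), with adjusted p of 0.0014, 0.0014 and 0.0016 over the list alone. Mecom, another stem cell transcription factor, rose 2.44-fold (1.29 ± 0.21, 0.0069), and its next brightest probe set gave -0.14. Mycn, a MYC family member, fell by 1.54 ± 0.17 (0.0014), where its next brightest probe set gave 0.25. Meis1, a cofactor of HOX proteins, was at 0.27 ± 0.15 and did not pass, with -0.12 from its next brightest probe set. The median was 0.25 with every probe set on its own, 0.28 with the mean over probe sets and 0.75 in the brighter part of the genes. The list's call ended with poly-A scaling (adjusted p = 0.70) and without normalization (0.12), where its median was 0.45 above the median gene in both cases and below 0 in absolute terms. With poly-A scaling, Hlf was at -1.06 and Mecom at -1.54, above the median gene at -2.57.

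Myeloid genes moved in both directions at 0.5 µg/ml. Ccr2 rose 4.25-fold (2.09 ± 0.13, adjusted p = 0.016 over all genes), and its next brightest probe set gave 2.21. Its call held under 6 of 17 alternatives and ended with the mean over its probe sets (1.80, adjusted p = 0.12). Ccr2 was at 0.99 in the values as deposited and at -0.64 with poly-A scaling, above the median gene at -0.94 and -2.57. Fcgr1 fell by 6.09 ± 0.28 on the log2 scale (adjusted p = 0.012), or by 5.33 with the offset, to a low intensity (5.42), while its next brightest probe set gave -0.59 and the mean over its probe sets -3.34 without passing (adjusted p = 0.21). In the list of monocytes, macrophages and dendritic cells 4 of 28 members rose and 3 fell when adjusted over the list alone. Clec10a, a macrophage lectin, rose by 3.25 ± 0.45 (adjusted p = 0.0046 over the list alone) and Irf8, a transcription factor of monocytes and dendritic cells, fell by 1.16 ± 0.26 (0.029). The list median was -0.23 (adjusted p = 0.67). Of 25 granulocyte genes, 5 rose and 3 fell when adjusted over the list alone. Chil3, a chitinase-like protein, rose by 3.29 ± 0.56 (0.012) and Gfi1 as above, while Prtn3, proteinase 3, fell by 1.46 ± 0.18 (0.0031) and Igsf6, an immunoglobulin superfamily receptor, fell by 2.24 ± 0.45 (0.019). The dimmer group of Chil3 and Igsf6 had means of 4.02 and 4.81, below the 25th percentile of intensity (4.95). The granulocyte list did not pass (median -0.09, mean -0.10, adjusted p = 0.97), and its test pointed upward where median and mean lay below 0.

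Nuclear genes of oxidative phosphorylation were lower at 0.5 µg/ml by small amounts. The median was -0.36 (SD 0.20 over members) and 32 of 34 members lay below 0 (camera adjusted p = 3.7e-11, 0.48 with an estimated correlation). Adjusted over the list alone, 7 members fell. Ndufa5 of complex I fell by 0.61 ± 0.12, Atp5o of the ATP synthase fell by 0.52 ± 0.10 and Cox5b of cytochrome c oxidase fell by 0.40 ± 0.07 (each adjusted p = 0.020 over the list alone), and the next brightest probe set of Ndufa5 gave -0.26. At 0.1 µg/ml the same list had a median of -0.01. Cell cycle genes were lower too, with a median of -0.17 and 30 of 38 members below 0 (adjusted p = 0.0011, 0.57 with an estimated correlation). No single member passed over the list alone. Plk1, a mitotic kinase, was at -0.74 ± 0.14, Kif11, a spindle motor, at -0.65 ± 0.16, and Rrm2, a subunit of ribonucleotide reductase, at 0.36 ± 0.09. The cell cycle median was -0.36 from the median gene with centred medians, on the deposited values and with poly-A scaling, and without the first array at 0.5 µg/ml the call ended (median -0.10, adjusted p = 0.28).

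Interferon-stimulated genes were higher at 0.5 µg/ml. The median was 0.61, with 21 of 26 members above 0 (camera adjusted p = 3.0e-04, 0.48 with an estimated correlation). Adjusted over the list alone, 6 members rose and 1 fell. Iigp1, an interferon-induced GTPase, rose 4.95-fold (2.31 ± 0.54, adjusted p = 0.033 over the list alone), Rsad2, the antiviral protein viperin, 3.24-fold (1.70 ± 0.31, 0.027) and Oasl2, an oligoadenylate synthetase relative, 2.85-fold (1.51 ± 0.27, 0.027). The next brightest probe set of Rsad2 gave 0.57, and with poly-A scaling the list's call ended (adjusted p = 0.44, median 0.46 above the median gene), where Oasl2 was at -1.26 and Rsad2 at -1.07. Genes of the integrated stress response had a median of 0.25 with 15 of 23 members above 0 (adjusted p = 0.0058, 0.63 with an estimated correlation). Of these Nupr1, a stress-induced chromatin protein, alone rose over the list alone, 7.24-fold (2.86 ± 0.34, adjusted p = 0.0048), and Ddit3, the transcription factor CHOP, was at 2.08 ± 0.50 without passing, with 0.23 from its next brightest probe set. The stress median was 0.53 in the brighter part of the genes and 0.15 with every probe set on its own. The stress call ended without normalization (adjusted p = 0.61), with centred medians (0.17) and with poly-A scaling (0.96), each with a median of 0.18 above the median gene. It also ended with any of 3 arrays left out, the first control (0.055, median 0.23) and the first (0.074, median 0.14) or second (0.063, median 0.43) array at 0.5 µg/ml. On the deposited scale the medians of both lists lay below 0 in absolute terms and above the median gene.

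All of these list shifts at 0.5 µg/ml went along with a poly-A spike-in level 3.09-fold, a Gapdh 3' to 5' ratio 1.73-fold and an Actb ratio 1.25-fold those of the controls.

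**Figure D2:**
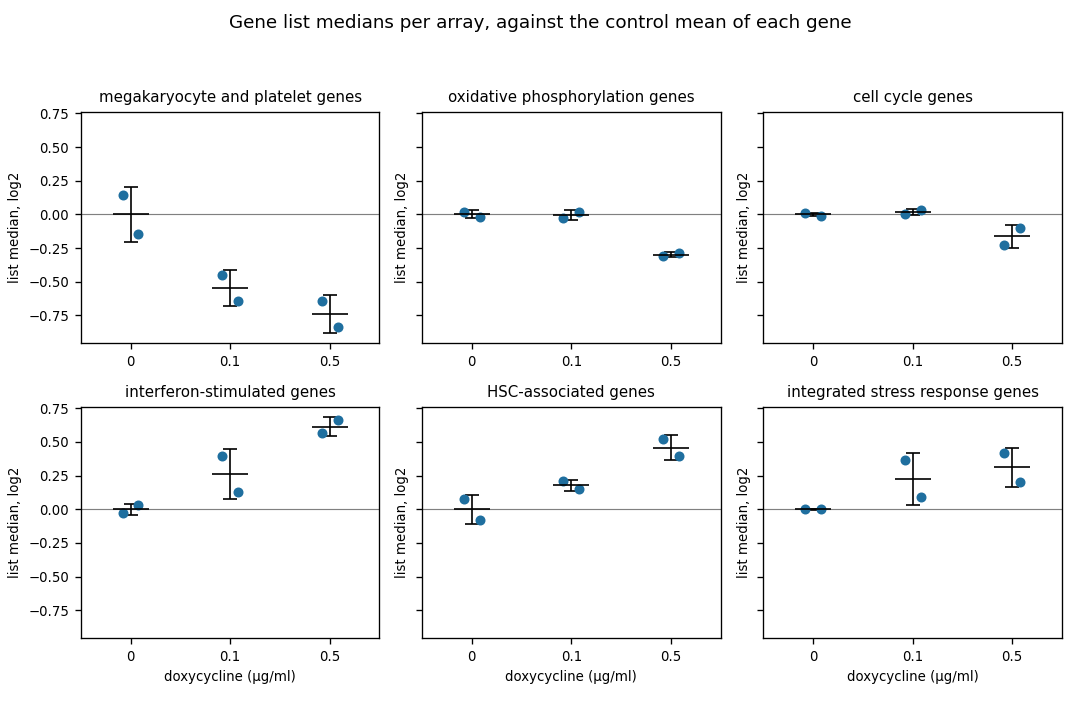
Median over each list of the log2 difference from the control mean of each gene, per array, against doxycycline in µg/ml, on quantile-normalized values. Points are arrays and bars the mean ± SD of 2 arrays. Megakaryocyte and platelet genes lay at -0.45 and -0.64 at 0.1 µg/ml and at -0.64 and -0.84 at 0.5 µg/ml, while oxidative phosphorylation genes left 0 only at 0.5 µg/ml (-0.31 and -0.29); the lists in the lower row turn below 0 at 0.5 µg/ml when the arrays are not normalized.

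Across all genes, 20 passed at 0.5 µg/ml, 9 of them higher and 11 lower. Besides those named and 3 that carry only clone or predicted names, Sprr1b rose by 5.07 ± 0.36 on the log2 scale (SE), Cyp2d22 by 4.72 ± 0.35, Pygm by 4.54 ± 0.27 and Tfap2a by 4.43 ± 0.34. Mamdc2, an extracellular matrix protein, rose by 3.76 and Cog2, a subunit of a Golgi tethering complex, by 2.51, though with poly-A scaling, which moved the median gene by -2.57, they were at 0.98 and -0.30. Atp1b1, a subunit of the sodium pump, fell by 6.66 ± 0.35 (adjusted p = 0.012), Edar, the ectodysplasin receptor, fell by 4.91, Abcc8, a sulfonylurea receptor, fell by 4.77 and Tcof1, the nucleolar protein treacle, fell 19.5-fold. Opn4 fell 12.2-fold, Cmc2, a mitochondrial protein, 5.18-fold and Scin, an actin-severing protein, 2.16-fold. Of 10 called genes with another probe set, 3 had it at least 2-fold apart in the same direction, and for Atp1b1, Abcc8, Cyp2d22 and Cmc2 it gave 0.09, 0.33, -0.47 and -0.32. It gave 1.01 for Tfap2a, -1.26 for Edar, -0.65 for Tcof1 and -0.24 for Opn4. The dimmer group of Sprr1b, Cyp2d22 and Edar had a mean log2 intensity of 3.81, 4.19 and 4.43, below the 25th percentile of 4.95, and that of Abcc8, Pygm, Atp1b1 and Tfap2a lay between 4.99 and 5.37, so the sizes of these 7 differences are uncertain. With the offset they were 3.51, 3.39 and -3.71, and -3.85, 3.73, -5.81 and 3.68 in the same order, and each still passed. The 17 named calls at 0.5 µg/ml each held under 6 to 10 of 17 alternatives. With the replicate number as a block, 4 genes passed at 0.5 µg/ml, 1 higher and 3 lower. With the mean over probe sets the calls ended for Atp1b1 (-1.83), Abcc8 (-2.22), Cyp2d22 (2.13), Cmc2 (-0.91), Tfap2a (1.86), Edar (-3.09), Tcof1 (-1.68) and Opn4 (-1.93), besides Ccr2 and Fcgr1.

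Several genes at 0.5 µg/ml stood just outside the threshold. Trp53inp1, a p53-induced stress protein, was at 1.79 ± 0.17, Plxnc1, a semaphorin receptor, at 1.92 ± 0.19, Setd1b, a histone methyltransferase, at 1.15 ± 0.11, and Cic, a transcriptional repressor, at -2.34 ± 0.22 (each adjusted p = 0.054). The next brightest probe sets gave -0.30 for Trp53inp1, -0.04 for Setd1b and 1.43 for Plxnc1. With poly-A scaling Trp53inp1 was at -1.001, Plxnc1 at -0.83 and Setd1b at -1.63, above the median gene at -2.57. Trp53inp1 rose over the list of p53 target genes alone (0.0013), a list that did not pass (median 0.24, adjusted p = 0.12). Dkk1, a secreted Wnt inhibitor, was at 3.62 ± 0.39 (adjusted p = 0.062), with 3.57 from its other probe set, and passed over the list of Wnt pathway genes alone (0.0030). The Wnt list as a whole did not pass (median 0.11, adjusted p = 0.12).

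By size alone, 1011 genes were at least 2-fold higher and 913 at least 2-fold lower at 0.5 µg/ml with no overlap between groups, and groups were apart for 42.5% of genes where chance gives 33.3%. These counts were 160 and 7966 in the values as deposited and 19 and 17098 with poly-A scaling. The total of 1924 became 3091 without the first control, 3510 without the first array at 0.5 µg/ml and 3170 without the second. In the values as deposited, 4358 genes passed, 50 higher and 4308 lower. With the arrays scaled to the poly-A spike-ins, 16392 genes passed, 13 higher and 16379 lower. With either control, either array at 0.1 µg/ml or the second at 0.5 µg/ml left out, at most 1 gene passed, and without the first array at 0.5 µg/ml 17 genes passed.

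**Figure D3:**
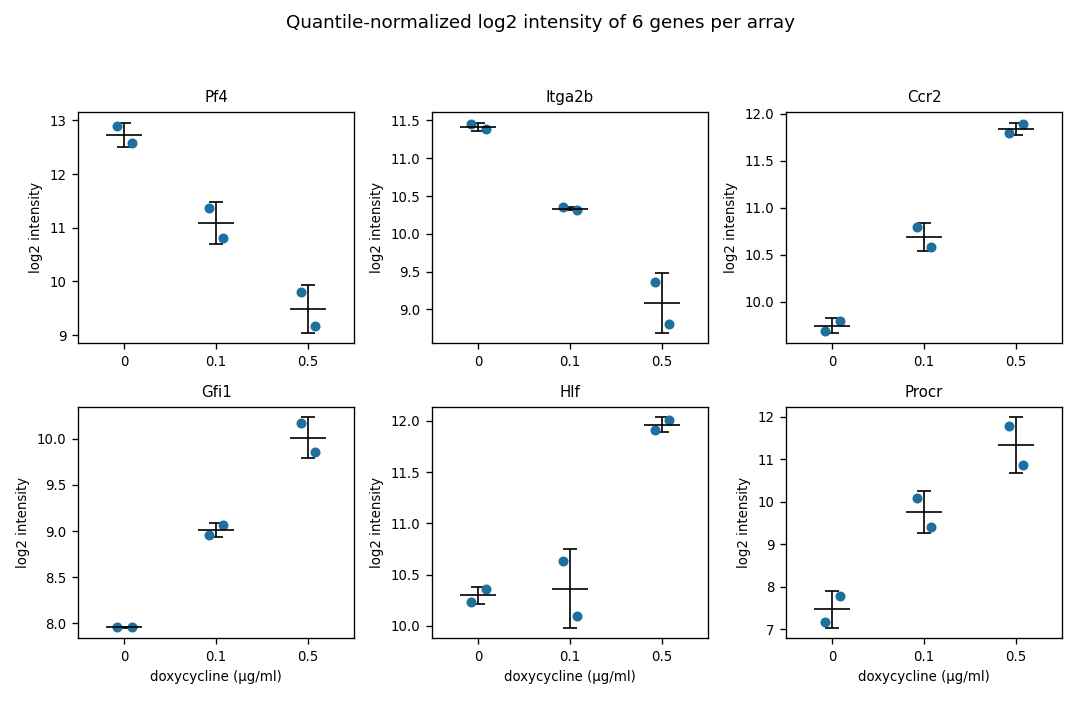
Quantile-normalized log2 intensity of 6 genes in each array, against doxycycline in µg/ml. Points are arrays and bars the mean ± SD of 2 arrays. Pf4 stood at 12.74, 11.09 and 9.49 on average and Ccr2 at 9.75, 10.69 and 11.84 with rising concentration; Hlf stood at 10.30, 10.37 and 11.96.

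Set directly against each other, the higher concentration had lower oxidative phosphorylation genes than the lower one (median -0.29, 33 of 34 members below 0, camera adjusted p = 2.0e-11). Ndufa5 fell by 0.68 ± 0.12 (SE, adjusted p = 0.021 over the list alone), among 8 members that fell. Stem cell genes were higher (median 0.37, adjusted p = 5.2e-04), with Hlf rising 3.02-fold (1.59 ± 0.19, adjusted p = 0.0077 over the list alone), Gfi1 rising 1.99-fold (0.99 ± 0.20, 0.032) while Mycn fell by 0.90 ± 0.17 (0.030). Interferon-stimulated genes were higher (median 0.36, adjusted p = 0.0012) and cell cycle genes lower (median -0.15, adjusted p = 0.0010). The interferon median was 0.18 with the mean over probe sets and 0.71 in the brighter part of the genes, and the cell cycle median -0.36 from the median gene with centred medians, on the deposited values and with poly-A scaling. Megakaryocyte and platelet genes were lower again (median -0.25, 18 of 24 members below 0, adjusted p = 0.024), where 4 members fell over the list alone. Pf4 fell by 1.60 ± 0.28 and Itga2b fell by 1.25 ± 0.21 (each 0.020 over the list alone). With an estimated correlation the adjusted p of these 5 lists lay between 0.48 and 0.72. The poly-A spike-ins were at 2105 against 745, the Gapdh 3' to 5' ratio at 3.92 against 2.42 and the Actb ratio at 2.21 against 1.70 in the same comparison. Within the granulocyte list, Chil3 rose by 3.22 ± 0.56 (0.019 over the list alone) from a low mean of 4.09 and Prtn3 fell by 1.62 ± 0.18 (0.0037), and in the monocyte list Ccr2 rose by 1.15 ± 0.13 (0.0022). With poly-A scaling, which moved the median gene by -2.17 here, Hlf was at -0.72, Gfi1 at -1.37 and Ccr2 at -1.17.

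Over all genes, 5 passed between 0.5 and 0.1 µg/ml. Cmbl (log2 6.13 ± 0.29) and C430002N11Rik (6.04 ± 0.35, named after its value was seen) rose, from means at 0.1 µg/ml of 4.55 and 4.38 that lay below the 25th percentile of 4.95. With the offset they gave 4.96 and 4.77. Both had fallen at 0.1 µg/ml, and at 0.5 µg/ml Cmbl had a log2 intensity of 10.68 ± 0.48 (SD) against 10.40 ± 0.03 in the controls. Atp1b1 (-5.29), Fcgr1 (-4.05) and Tcof1 (-3.12) fell (each adjusted p = 0.0497), where their next brightest probe sets gave -0.36, -1.94 and 0.02. With the offset they gave -4.47, -3.33 and -2.92, and the calls of Fcgr1 (adjusted p = 0.072) and Tcof1 (0.051) ended. With the mean over probe sets the calls of Atp1b1 (-1.64), Fcgr1 (-2.99) and Tcof1 (-1.01) ended, and the 5 calls held under 5 to 10 of 17 alternatives. The calls of Atp1b1, Fcgr1 and Tcof1 also ended with the replicate number as a block. Without the first array at 0.5 µg/ml 8 genes passed, and without any other at most 1. The stem cell call, with a median of 0.37, ended on the deposited values (adjusted p = 0.21, 0.36 above the median gene), with poly-A scaling (0.995, also 0.36) and without the first array at 0.5 µg/ml (0.097, 0.35), where the cell cycle call ended as well (median -0.10, 0.31); without the second array there the cell cycle median was -0.27. The megakaryocyte call, with a median of -0.25, ended without the first (adjusted p = 0.12) or second (0.11) control, with a median of -0.17 each. It ended without the first array at 0.1 µg/ml (0.059, median -0.34) or the second at 0.5 µg/ml (0.23, median -0.24), and with centred medians (0.076) and poly-A scaling (0.24), where the list lay at -0.29 from the median gene. Without the first array at 0.5 µg/ml its median was -0.44. The interferon call, with a median of 0.36, ended on the deposited values (0.069) and with poly-A scaling (0.76), at 0.38 above the median gene in both.

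The responses to both concentrations were set against each other across genes. Their log2 differences against the control correlated with r = 0.52 and a covariance of 0.288 over 18181 genes, which are not independent replicates. Both comparisons use the same controls, and unchanged groups simulated against shared controls gave a mean r of 0.50, at most 0.54, and a mean covariance of 0.226, at most 0.253. The observed r lay within the simulated range and the observed covariance above it. Noise in these simulations was independent between genes, so their range may be too narrow for real arrays. The place of the covariance therefore does not show a shared response. The sign was shared by 65.1% of genes, against a mean of 66.7% in the simulations. With a separate control for each concentration, r was 0.090 or 0.050 and the covariance 0.0687 or 0.0397, with 1 control on each side. Of the 2 genes called higher at 0.1 µg/ml, Pygm and 4933411E08Rik, both were also among the 9 called higher at 0.5 µg/ml, and the calls for lower genes shared 0. Independent lists of these lengths would share 9.9e-04, a value that leaves out the shared controls. Unchanged groups simulated against shared controls gave lists of the same lengths, taken by p, that shared 0.76 genes on average and 2 in 10 of 50 simulations, so part of the shared calls may come from the shared controls.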

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

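The tests of poly-A spike-in level at 0.1 µg/ml, of the 3' to 5' ratio, of the next brightest probe sets and of other splits of the arrays were chosen after the results were seen. The comparisons with matched random lists were set before their own outcome was seen. They cover only lists that had already passed against the control, so these lists were taken after the list tests.

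The poly-A spike-ins stood out because they belong to no comparison and were 3.09-fold higher at 0.5 µg/ml than in the controls. The Gapdh 3' to 5' ratio, read from control probe sets, stood out in the same way at 1.73-fold, as did the Actb ratio at 1.25-fold. The hybridisation spike-ins, normally added after labelling, were 0.983-fold at 0.5 µg/ml.

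The lower megakaryocyte and platelet list at 0.1 µg/ml was set against technical causes. Its median of -0.55 lay at percentile 0 of 10000 random lists matched on mean expression, whose central 95% ran from -0.08 to 0.23. Genes of like intensity thus did not share the shift. The list had already passed against all genes, and quantile normalization holds matched lists near the median gene. A place outside their range was therefore likely beforehand and does not bear on other array effects. Less starting RNA would need the poly-A spike-ins to rise by 1.17 on the log2 scale, in proportion to the list, and they rose by 0.126 ± 0.239 (SE). The value of 1.17 takes the whole list shift at 0.5 µg/ml as an effect of RNA amount, which was not tested. The comparison bears on that reading only and cannot exclude another effect of RNA amount at 0.1 µg/ml. No test bore on a response to HOXA10, whose induction was not seen at this setting in mouse probe sets that may not read the transgene (log2 differences of 0.31 and -0.60, limma adjusted p = 0.991 and 0.986 with every probe set tested on its own, and 0.97 for the brighter over all genes). That response and an effect of doxycycline itself stay open as untested.

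The list shifts at 0.5 µg/ml were weighed in the same way. Against random lists matched on mean expression, the percentile was 0 for oxidative phosphorylation genes and 0 for megakaryocyte and platelet genes. It was 99.99 for interferon-stimulated genes, 99.99 for stem cell genes, 0.53 for cell cycle genes and 99.1 for stress response genes. Genes of like intensity thus did not share these shifts. All 6 lists had already passed against all genes on normalized values, so this result was likely beforehand and does not bear on other array effects. Less RNA or more 3' biased RNA cannot be told apart from the concentration, because the lowest Gapdh 3' to 5' ratio at 0.5 µg/ml was 3.28 and the highest of the other arrays 2.49. The Actb ratio set them apart far less, at 1.90 against 1.85. RNA yield or quality, HOXA10 and doxycycline itself could each account for these shifts, and for those between 0.5 and 0.1 µg/ml.

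The very large differences of single genes at 0.5 µg/ml may be faults of single probe sets. Of 7 called genes with a bright next probe set, 3 had it 2-fold or more apart the same way (exact 95% interval 9.90% to 81.6%), which leaves this open. The first reading set for this test would have taken 3 of 7 for such faults, and the interval replaced it after the count was seen. The real split of the 6 arrays into 3 pairs called 22 genes in any comparison and the highest of the other splits 12. The real split was the 1 with as many among 15, and so few splits cannot give a share below 0.05.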

How the results depend on the processing

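Scaling to the poly-A spike-ins and the count over 2 probe sets were chosen after the data were seen. Under each alternative the 12 called lists held their direction relative to the median gene, and an estimated correlation ended all 12 calls. Scaling lost 4 list calls as deposited, 2 with medians centred and 6 with poly-A scaling. Leaving out an array lost 2 (first control), 1 (second control), 1 (first at 0.1 µg/ml), 0 (second), 4 (first at 0.5 µg/ml) and 2 (second). In absolute terms 46 of 81 list medians changed sign as deposited (5 of the 12 called) and 48 with poly-A scaling (5 of 12), as did 56 and 123 of 372 gene differences; directions here are relative to the median gene for lists, a choice made after the absolute values were seen. The cause was not tested unless stated. A robust prior was not run for lists, since camera takes none, and the brighter part of the genes gave 78 of 81 list tests. Of 26 named gene calls, 26 held as deposited, 23 with a robust prior, 13 with the mean over probe sets, 8 with the block, 6 without a trend and 0 with only the groups compared. Leaving out an array ended all 26, except that 7 held without the first array at 0.5 µg/ml. Arrays carry no depth; dim probe sets limit small changes.

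The replicate number as a block gave 4 genes (1 higher, 3 lower) at 0.5 against 0 and 3 (3, 0) at 0.5 against 0.1 µg/ml. It gave 4 at 0.1 against 0, and changed no list call. The main fit had no block because the series' design text names none. Same-numbered arrays deviated together with correlations of 0.03, 0.05 and -0.01. Each group gives a single deviation, so this does not settle whether the numbers mark pairs.

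In the order 0.1 against 0, 0.5 against 0 and 0.5 against 0.1 µg/ml, the main counts were 4, 20 and 5 genes, 1519, 1924 and 1740 (980, 760) genes 2-fold apart, and 1 (0 higher, 1 lower), 6 (3, 3) and 5 (2, 3) lists. As deposited they were 11 (3 higher, 8 lower), 4358 (50, 4308) and 12 genes, 1871 (275, 1596), 8126 (160, 7966) and 4974 (325, 4649) apart, and 10 (3, 7) and 9 (1, 8) lists for the last 2. Centred medians gave 11 (4, 7), 25 and 10 genes, 1991 (922, 1069) apart at 0.5 against 0.1 and 3 (2, 1) lists at 0.1 against 0. Poly-A scaling gave 12 (3, 9), 16392 (13, 16379) and 15012 (15, 14997) genes, 2219 (204, 2015), 17117 (19, 17098) and 16471 (43, 16428) apart, and 2 (1, 1), 12 (4, 8) and 8 (1, 7) lists; the arrays' poly-A levels set these by construction. Without a trend 0, 7 and 0 genes passed, and with only the groups compared 0, 0 and 0. An adjusted p of 0.10 gave 11, 109 (68 higher, 41 lower) and 30, where the main 20 were 9 higher and 11 lower. The brighter part of the genes gave 10, 65 and 5 genes, 511, 704 and 607 apart, from fewer genes tested, and 2 lists at 0.1 against 0. The offset gave 861, 1065 and 887 apart and 3 genes at 0.5 against 0.1. The mean over probe sets gave 8 genes at 0.1 against 0, and every probe set on its own 8 at 0.5 against 0.1. An estimated correlation gave 0, 0 and 0 lists. Group means 2-fold apart without a test gave 2069, 2564 and 2308 genes. Among the 9000 genes with more than 1 probe set, both of the brightest were 2-fold apart for 118 (83 higher, 35 lower) at 0.5 against 0. Of these, 2 had a limma adjusted p below 0.05. The same count gave 16 higher and 30 lower at 0.1 against 0, and 55 higher and 29 lower at 0.5 against 0.1. Of them 0 and 1 passed. Over all genes, 2881, 3965 and 3703 were apart at 1.5-fold, and 683, 756 and 620 at 3-fold. Leaving out an array gave 0 to 1, 0 to 17 and 0 to 8 genes, 1524 to 2654, 1910 to 3510 and 1676 to 3632 apart, and 1 to 2, 4 to 7 and 3 to 8 lists; the 17, 8, 3510 and 3632 came without the first array at 0.5 µg/ml and the 2654 without the first control. Every array of the 2 groups compared raised the counts apart, since a group of 1 array overlaps less by construction.

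The correlation of both responses was 0.52. It was 0.51 with the mean over probe sets, 0.50 over the arrays numbered 2 alone, a number not shown to mark 1 experiment, 0.090 and 0.050 with separate controls, and 0.39 to 0.69 with an array left out.

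Among named genes and lists that passed in either setting, with lists read relative to the median gene, these directions turned. As deposited, at 0.5 against 0, Meis1 was -0.89 and Rrm2 -0.69. The ribosomal protein list was 0.29 above the median gene at 0.5 against 0 as deposited, centred and with poly-A scaling, and the list of G1 regulators -0.16 at 0.5 against 0.1 as deposited and with poly-A scaling. With poly-A scaling at 0.5 against 0, Cog2 was -0.30, Ccr2 -0.64, Mettl7a1 -1.49, Setd1b -1.63, Trp53inp1 -1.001, Plxnc1 -0.83, Hlf -1.06, Meis1 -2.52, Mecom -1.54, Flt3 -1.61, Hoxa9 -2.41, Rrm2 -2.31, Txnip -2.15, Cdkn1c -1.44, Oasl2 -1.26, Rsad2 -1.07 and Csf2ra -1.61. At 0.5 against 0.1 Setd1b was -1.22, Gfi1 -1.37, Hlf -0.72, Meis1 -2.06, Mecom -1.56 and Ccr2 -1.17. That scaling moved the median gene by -2.57 and -2.17.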

Other observations

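No test in this part was added after the results were seen, apart from poly-A scaling. At 0.5 µg/ml, single genes of eosinophils and mast cells fell without their lists passing. In the eosinophil list (7 measured, median -0.91, adjusted p = 0.28), 2 members fell when adjusted over the list alone. The list median was -0.31 without the first and -1.54 without the second array at 0.5 µg/ml. Ccr3, the eotaxin receptor, fell by 2.46 ± 0.52 (SE) and Siglecf, an eosinophil lectin, fell by 1.68 ± 0.31 (each 0.013), Ccr3 to a mean log2 intensity of 3.35, below the 25th percentile of 4.95. In the mast cell and basophil list (19 measured, median 0.04, mean -0.35, adjusted p = 0.81) Gzmb, granzyme B, fell by 2.95 ± 0.51 (0.027). Values in this part are quantile-normalized unless another scaling is named.

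Of 24 Wnt pathway genes, Fzd4, a Wnt receptor, rose 4.06-fold at 0.5 µg/ml (log2 2.02 ± 0.38, adjusted p = 0.028 over the list alone) beside Dkk1, and its next brightest probe set gave 0.61. Among G1 regulators Txnip, a thioredoxin-binding protein, rose 1.59-fold (0.67 ± 0.13, 0.029) while Mycn fell by 1.54 ± 0.17 (0.0028), and the list did not pass (median -0.02, mean 0.00, adjusted p = 0.99). Among receptors of cytokines, Flt3 was at 1.22 ± 0.29, Csf2ra at 1.22 ± 0.31 and Il6st at 1.59 ± 0.46, none past the threshold over this list alone, though Flt3 rose over the list of monocytes, macrophages and dendritic cells alone (0.029), and the other probe sets gave -0.35 for Csf2ra and -1.55 for Il6st. Within the Hox list (26 measured, median 0.20, adjusted p = 0.33), Hoxa9 was at 0.31 ± 0.12. Genes earlier described as HOXA10 targets gave a median of 0.18 and a mean of -0.01 (11 measured, adjusted p = 0.96), and 1 member fell over the list alone. With poly-A scaling, which moved the median gene by -2.57, Txnip was at -2.15, Flt3 at -1.61, Csf2ra at -1.61 and Hoxa9 at -2.41. Lists of B cells (median 0.11, adjusted p = 0.97, with the test pointing downward) and of T and NK cells (0.33, 0.83) did not pass.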
